A study of Canis lupus familiaris with 6 samples.

How the data were processed

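RNA was measured in 6 libraries of canine adipose-derived stem cells, the fibroblast-like precursor cells isolated from dog fat, after 14 days in an adipogenic medium. Per the labels, 3 libraries came from cells that received the solvent DMSO (called control here) and 3 from cells that received 1 µM bisphenol A (BPA), a monomer of polycarbonate plastics that binds oestrogen receptors. The medium was added after 2 days of culture. It held 1 µM dexamethasone, a glucocorticoid, 200 nM rosiglitazone, an agonist of the adipogenic receptor PPARG, and 10 µg/mL insulin. Groups and replicate numbers were taken from the labels. The labels do not say whether replicates are separate cultures or animals, so no p-value reaches beyond these samples, whose spread may be technical.

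Per the labels' protocols, total RNA was extracted on silica columns and made into stranded, poly(A)-selected mRNA libraries for Illumina sequencing. The authors deposited 1 table of log2 values for 23299 genes, named as normalized log TPM. TPM is the transcript abundance of a gene as a share of its library's total, scaled to 1000000. Raising 2 to each deposited log2 value and subtracting 1 gave a sum of 1000000 in each of the 6 columns, so the values were read as log2(TPM + 1), with a pseudocount of 1. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Since the build is not named, no coordinates are printed. TPM keeps no read depth, so the depth behind each value is unknown and no counting interval can be given. A TPM is a share of each library's total: a gene can lie lower because others lie higher. Whether reads shared between near-identical genes were split or dropped is also not given. Values of ribosomal protein genes, metallothioneins, olfactory receptor genes and clustered chemokine genes are therefore uncertain. Of the 23299 names, 22346 were symbols in an NCBI gene table of the dog assembly UU_Cfam_GSD_1.0, which was used only for names and synonyms. Locus numbers made up 8537 of the names.

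Genes with a mean log2(TPM + 1) of at least 1 over the 6 libraries were tested, which left 12277. BPA was compared with control by limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend on expression, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are differences on the log2(TPM + 1) scale, which understates the change of genes with few transcripts; means and SDs are in TPM over 3 libraries. A total of 39 gene lists for adipocytes, metabolism, hormone and stress responses and other cell types were fixed before the data were examined. The 32 lists with at least 5 tested members were tested with limma's camera, which compares a list with the other tested genes. It was run at a preset inter-gene correlation of 0.01. At that setting it takes genes as nearly independent, so its p-value is not a measure of the spread between libraries. Camera was repeated with the correlation estimated from the data, and limma's fry tested whether a list's genes moved, on balance, in 1 direction. A list's mean per library is the mean over its tested genes of log2(TPM + 1) minus the control mean, compared by an exact two-sided permutation test whose smallest possible p with 3 against 3 libraries is 0.1. Genes were also adjusted over the members of their list alone. That adjustment makes no correction across the lists.

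The rule for named genes was also fixed in advance. It asked for genes past the threshold. Since none passed, it took the 10 genes of smallest p in each direction and up to 2 members of smallest p per list. A fixed set of adipocyte, cytokine and receptor genes was included whatever their p. Locus numbers were passed over, 1 among the higher genes and 3 among the lower. GPER1, in the fixed set, was not analysed here. Genes named outside the rule were chosen after their values were seen, and the text says so at each.

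Alternatives fixed in advance for values and scaling were no filter, a stricter filter (mean of at least 3), pseudocounts of 0.1 and 5, median centring, quantile normalization, median-ratio scaling and rescaling without the 20 most abundant genes. Those for the model were empirical Bayes without a trend or made robust, limma array weights, the replicate number as a block, leaving out each library in turn, and other thresholds. A further pair, the first principal component as a covariate and leaving out BPA replicate 3 with control replicate 2, was added after seeing the data. The test was checked on data simulated for the comparison of BPA with control over all 12277 tested genes, with 200 genes changed by known amounts. It recovered 66% of genes changed by a log2 of 1, 88% at 2, 94% at 3 and 98% at 4 with independent noise, where 19 unchanged genes were called. With the main shared axis of these libraries added to the noise it recovered 24%, 76%, 92% and 88%, and 1 unchanged gene was called. A further list of 25 genes was raised by a log2 of 1. Each kind of noise was drawn once, and scores on the shared axis were drawn at random, with no library set apart. No change under a log2 of 1 was simulated, so recovery of smaller changes, as many named here are, is unknown. Figures were drawn with matplotlib 3.10.9.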

Results

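Messenger RNA of canine adipose-derived stem cells was profiled after 14 days of adipogenic differentiation with solvent (control, n = 3 libraries) or with 1 µM BPA (n = 3), in a study of the effects of BPA on obesity in dogs. The table gave log2(TPM + 1) for 23299 genes, of which 12277 were tested. Between 19649 and 20321 genes had a value above 0 in each library, and between 12159 and 12584 reached 1 TPM. The 20 most abundant genes of a library took from 16.8% to 18.1% of its TPM. No 2 libraries held the same values: correlations of log2(TPM + 1) across tested genes, which are not independent replicates, ranged from 0.928 (BPA replicates 1 and 3) to 0.994 (control replicates 1 and 3).

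The libraries did not separate by treatment along their main axis of variation. The first principal component took 79.8% of the variance between libraries. Its scores were -28.1, 11.3 and -14.4 in control replicates 1, 2 and 3 and -29.9, -0.10 and 61.1 in BPA replicates 1, 2 and 3. BPA replicate 3 thus stood apart from the others, followed by control replicate 2. The second component, with 7.44% of the variance, held the 3 BPA libraries at 14.6, 9.18 and 1.68 and the 3 control libraries at -8.26, -5.62 and -11.6.

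**Figure D1:**
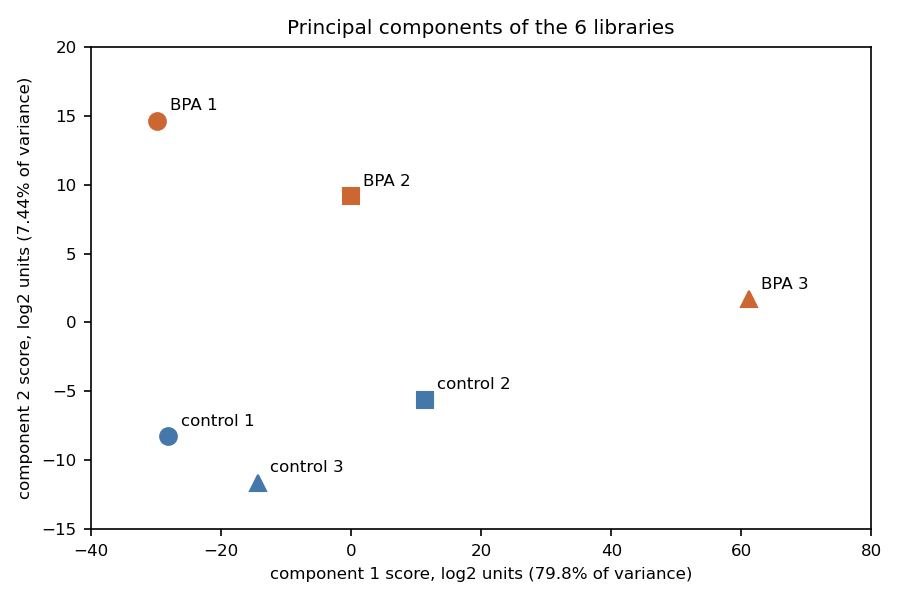
Scores of the 6 libraries on the first principal component (horizontal axis, log2 units, 79.8% of variance) and the second (vertical axis, log2 units, 7.44%), with control in blue and BPA in orange. BPA replicate 3 lies at 61.1 on the horizontal axis, and on the vertical axis all BPA libraries lie above all control libraries.

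The comparison of BPA with control asked how BPA alters gene expression in differentiating fat cells. Several adipocyte genes lay above control. Adiponectin (ADIPOQ), the hormone secreted by mature adipocytes, averaged 33.0 ± 7.13 TPM (SD, n = 3) with BPA and 10.7 ± 3.53 TPM in control, a log2 change of 1.55 (SE 0.26). CIDEC, which promotes the fusion of lipid droplets, averaged 6.65 ± 1.46 against 2.17 ± 0.44 TPM, and PCK1, an enzyme of glyceroneogenesis, 11.7 ± 2.15 against 4.12 ± 1.31 TPM. Below control lay the carbonic anhydrases CA12 at 11.7 ± 0.50 against 21.4 ± 1.90 TPM and the hypoxia-induced CA9 at 5.82 ± 1.15 against 11.4 ± 0.70 TPM. As groups, adipocyte, lipogenic and glucocorticoid-responsive genes were higher with BPA, and glycolytic and hypoxia genes, inflammatory genes and ribosomal protein genes lower, by limma's camera with a preset correlation. These 6 calls were lost with an estimated correlation (adjusted p from 0.323 to 0.815), and 3 of them also ended when a library was left out: the ribosomal call without BPA replicate 3, the glycolysis call without BPA replicate 1 and the inflammatory call without BPA replicate 1 or 2.

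No single gene passed. By limma with Benjamini-Hochberg adjustment 0 genes were higher and 0 lower, and the smallest adjusted p was 0.901. At an unadjusted p under 0.05 there were 439 genes, 230 higher and 209 lower, where chance gives about 614. Without BPA replicate 3 there were 684 such genes, so the comparison with chance depended on that library. All 3 BPA libraries lay above all 3 control libraries for 661 genes and below them for 489, together 9.37% of tested genes, where chance gives 10%. The median SE of a gene's log2 change was 0.15. With an estimated correlation 0 of the 32 tested lists passed in camera (4 at an unadjusted p under 0.05), and by fry 0 passed (3 unadjusted).

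The 10 genes of smallest p among those higher with BPA, named although none passed, had every BPA library above every control library. Besides ADIPOQ, CIDEC and PCK1 they included HCAR2, the niacin receptor that restrains lipolysis (3.04 ± 0.18 against 1.13 ± 0.32 TPM, log2 change 0.93, SE 0.13). GLUL, which makes glutamine, averaged 281 ± 12.2 against 188 ± 18.6 TPM (log2 change 0.58, SE 0.10). SCD, the desaturase that forms oleate, averaged 482 ± 42.1 against 281 ± 49.99 TPM (log2 change 0.79, SE 0.15). CRYBG3, SCUBE2, TSC22D1 and SPAAR followed, with log2 changes of 0.51 (SE 0.09), 0.57 (SE 0.10), 0.49 (SE 0.09) and 0.54 (SE 0.10). Of the 10 lower genes, again with no overlap between groups, CA12 had a log2 change of -0.82 (SE 0.10) and CA9 of -0.88 (SE 0.15). DKK1, a secreted Wnt antagonist, averaged 363 ± 29.1 TPM with BPA and 567 ± 14.1 TPM in control (log2 change -0.65, SE 0.09). BNIP3, a mitochondrial protein induced by hypoxia, averaged 473 ± 23.3 against 651 ± 38.7 TPM. The protease inhibitor SERPINE2 had a log2 change of -0.48 (SE 0.07), the secreted peptide genes PTHLH and NMB -0.68 (SE 0.12) and -0.77 (SE 0.15). The retinoic acid binding protein CRABP2 was at -0.75 (SE 0.15) and RBM11 at -0.65 (SE 0.13). OR5AN5P, an olfactory receptor pseudogene whose reads may be shared with related genes, was at -1.39 (SE 0.26). Each of these 20 genes had an adjusted p of 0.901 by limma.

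**Figure D2:**
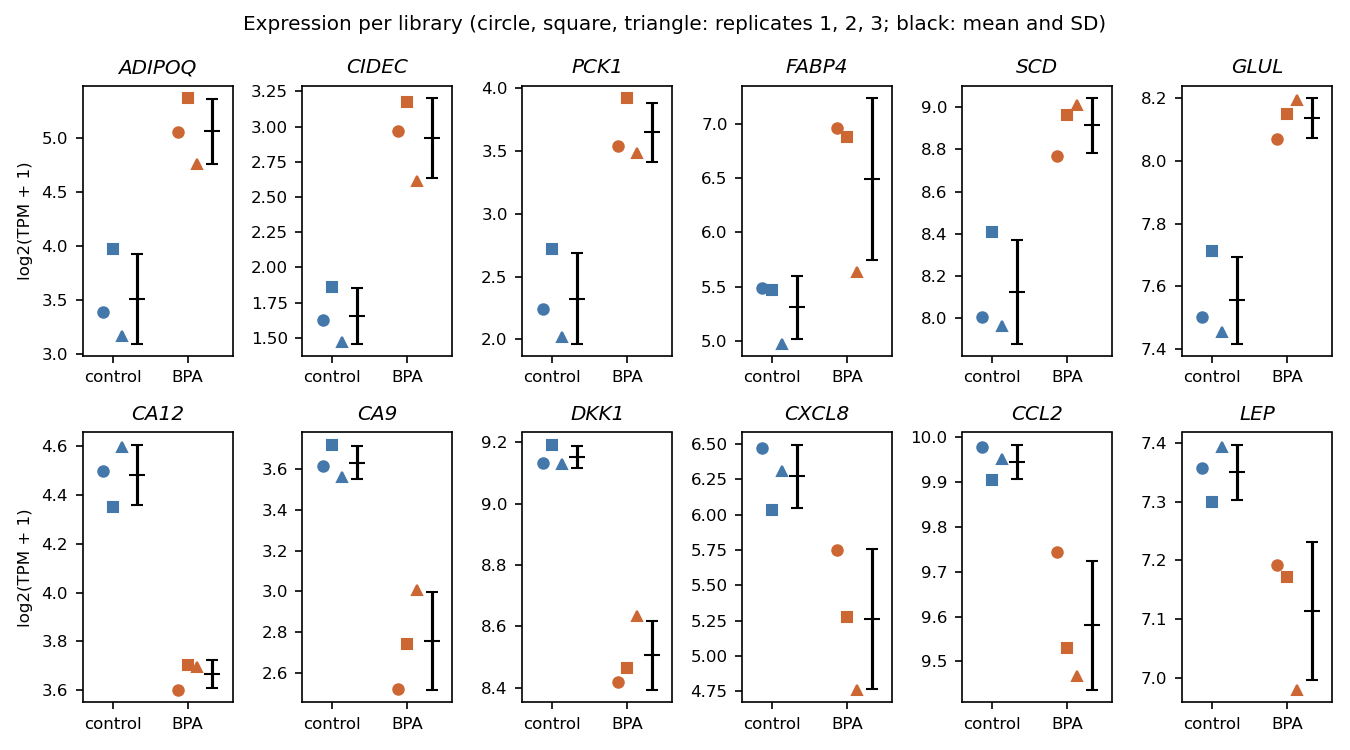
Log2(TPM + 1) (vertical axis, scaled per gene and not starting at 0) of 12 named genes in the 3 control libraries (blue) and the 3 BPA libraries (orange), with symbols for replicates and black bars for the mean and SD. For each gene shown the groups do not overlap, and the adjusted p of each by limma is 0.901. Named genes whose groups overlap, such as LPL and FASN, are not shown. Of all tested genes 9.37% had no overlap, where chance gives 10%.

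The adipocyte and lipid droplet list was higher with BPA: 18 of its 25 tested members lay above control, with a median log2 change of 0.55 (camera, adjusted p = 6.35e-05). Its adjusted p was 0.323 with an estimated correlation. The list's mean was 0.38, 0.60 and 0.55 above the control mean in BPA replicates 1, 2 and 3 and -0.07, 0.19 and -0.12 in control replicates 1, 2 and 3 (exact permutation p = 0.1, the smallest possible). For the means of the other 5 lists that passed camera the exact permutation p was 0.2 (fatty acid synthesis and glucocorticoid), 0.4 (inflammatory) and 0.5 (glycolysis and ribosomal), and it was also 0.1 for the thermogenic and NRF2 lists, which did not pass camera. At an unadjusted p under 0.05 there were 9 members higher and 4 lower, 0 passed over all genes tested, and 4 passed when adjusted over the list alone. FABP4, the fatty acid carrier of adipocytes, averaged 96.4 ± 41.5 against 39.2 ± 7.58 TPM (log2 change 1.18, SE 0.39). PLIN1, which coats lipid droplets, averaged 5.68 ± 2.51 against 1.61 ± 1.10 TPM (log2 change 1.35, SE 0.40). These 4 lower members included the satiety hormone gene LEP, at 138 ± 11.04 against 162 ± 5.31 TPM. The others, named after their values were seen, were HILPDA, RBP4 and CAV1, with log2 changes of -0.44 (SE 0.12), -0.35 (SE 0.11) and -0.32 (SE 0.12). Lipoprotein lipase (LPL) overlapped between groups at 515 ± 92.7 and 447 ± 48.2 TPM. The call ended under the stricter expression filter, where the median was 0.16 and the adjusted p 0.760. Several higher members had few transcripts, of unknown depth: CIDEC, PCK1 and PLIN1 averaged 2.17, 4.12 and 1.61 TPM in control. The higher ADIPOQ and FABP4 averaged 10.7 and 39.2 TPM there. The 4 lower members were more abundant, with LEP at 162, HILPDA at 827, RBP4 at 357 and CAV1 at 190 TPM in control. Over all alternatives the adjusted p ranged from 1.41e-07 to 0.760. Without BPA replicate 3 the median was 0.33, with 20 of 25 members above control.

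Fatty acid and triglyceride synthesis genes were also higher as a list, with 17 of 20 members above control and a median log2 change of 0.33 (camera, adjusted p = 0.00017; adjusted p = 0.815 with an estimated correlation). SCD had the smallest p of this list by limma and was the 1 member that passed when adjusted over the list alone, against 0 over all genes. LPIN1, which makes diacylglycerol, averaged 1.58 ± 0.24 against 0.99 ± 0.07 TPM, and fatty acid synthase (FASN) overlapped at 66.1 ± 66.6 and 29.8 ± 19.3 TPM. BPA replicate 3 had the highest list mean, 0.67, and without it the median was 0.09 (0.20 without control replicate 1). Adipogenic transcription factors had 12 of 13 members above control (median 0.41, adjusted p = 0.0591), but 6 of 13 without BPA replicate 3 (median -0.0007), whose list mean was 0.98. EBF1 averaged 1.88 ± 0.12 against 1.42 ± 0.11 TPM and NR1H3 5.86 ± 0.43 against 6.85 ± 0.61 TPM. CEBPA overlapped at 8.41 ± 5.65 and 5.40 ± 2.07 TPM. PPARG, the receptor targeted by rosiglitazone, lay under the expression filter and was not tested. It averaged 0.275 ± 0.096 TPM in the BPA libraries, all above the control libraries at 0.115 ± 0.015 TPM.

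Glucocorticoid-responsive genes were higher with BPA in medium that held dexamethasone in both groups: 20 of 23 tested members lay above control, with a median log2 change of 0.32 (camera, adjusted p = 9.64e-07; adjusted p = 0.323 with an estimated correlation). At an unadjusted p under 0.05 there were 6 members higher and 0 lower. Over all genes 0 passed, and 1, GLUL, did when adjusted over the list alone. PDK4, which restrains pyruvate oxidation, averaged 207 ± 9.89 against 149 ± 19.4 TPM (log2 change 0.47, SE 0.12). FKBP5, TSC22D3 and SGK1, named after their values were seen, changed less, by 0.19 (SE 0.09), 0.11 (SE 0.07) and 0.15 (SE 0.08). PER1 and DUSP1, also named after their values were seen, overlapped between groups. The list shares members with others, such as PDK4 with fatty acid oxidation and PIK3R1 with insulin handling, so these lists are not independent. Lists that passed camera overlap too. The glucocorticoid list shares ANGPTL4 with the adipocyte list, and NFKBIA and SAA1 with the inflammatory list. Of these, ANGPTL4 and NFKBIA were named after their values were seen. List means were 0.10, 0.26 and 0.43 in BPA replicates 1, 2 and 3, and 0.13 in control replicate 2. Without BPA replicate 3 the median was 0.17, with 20 of 23 members above control, and 10 were higher and 0 lower at an unadjusted p under 0.05.

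Glycolysis and hypoxia genes were lower with BPA, with 18 of 27 members below control and a median log2 change of -0.09 (camera, adjusted p = 1.79e-05; adjusted p = 0.323 with an estimated correlation). At an unadjusted p under 0.05 there were 7 lower and 0 higher; 0 passed over all genes and 2, CA9 and BNIP3, adjusted over the list alone. The abundant glycolytic enzymes ENO1 and TPI1, named after their values were seen, averaged 848 ± 8.85 against 994 ± 15.9 TPM and 1744 ± 54.2 against 2067 ± 58.2 TPM. Other abundant enzymes, also named after their values were seen, were mixed. PGAM1 lay lower without overlap, but GAPDH (995 ± 170 and 1049 ± 76.1 TPM), ALDOA (1544 ± 252 and 1633 ± 131 TPM) and LDHA (1570 ± 339 and 1942 ± 190 TPM) overlapped between groups. List means were -0.28 and -0.16 in BPA replicates 1 and 2 but 0.09 in BPA replicate 3. Without BPA replicate 3 the median was -0.21, with 24 of 27 members below control. It was -0.14 without control replicate 1 and -0.04 without control replicate 2. Without BPA replicate 1 the call ended (median -0.05, adjusted p 0.0752, in a range over alternatives from 2.25e-15 to 0.745).

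Inflammatory cytokine and chemokine genes were lower as a list by a small margin, with 15 of 26 members below control and a median of -0.07 (camera, adjusted p = 0.0214; adjusted p = 0.323 with an estimated correlation). The neutrophil chemokine CXCL8 averaged 38.9 ± 13.4 against 76.8 ± 11.7 TPM (log2 change -1.01, SE 0.27). The monocyte chemokine CCL2 averaged 767 ± 78.4 against 984 ± 25.9 TPM (log2 change -0.36, SE 0.10), and IL11 1.10 ± 0.10 against 1.75 ± 0.12 TPM. None of these 3 overlapped between groups. IL6 overlapped at 1.12 ± 0.41 and 1.77 ± 0.48 TPM. At an unadjusted p under 0.05 there were 5 members lower and 1 higher, CXCL12 at 35.3 ± 3.29 against 27.4 ± 3.14 TPM. Of the members 0 passed over all genes or adjusted over the list alone. The call ended without filter (adjusted p 0.0902), under the stricter filter (0.149), without BPA replicate 1 (median 0.0028, adjusted p 0.260) and without BPA replicate 2 (0.0700). Without BPA replicate 3 the median was -0.19 and without control replicate 2 it was -0.05, and over all alternatives the adjusted p ranged from 1.37e-05 to 0.745. Leaving out BPA replicate 3 also gave 8 members lower and 3 higher at an unadjusted p under 0.05.

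Ribosomal protein genes lay below control for 46 of 47 members (median -0.21; camera, adjusted p = 2.04e-09; adjusted p = 0.815 with an estimated correlation). By limma 0 members had an unadjusted p under 0.05, and 0 passed over all genes or adjusted over the list alone. RPL38 averaged 87.0 ± 11.8 against 106 ± 9.77 TPM and RPS19 489 ± 103 against 608 ± 70.4 TPM, values that are uncertain because these genes have many near-identical copies. The list mean followed the first component, at -0.56 in BPA replicate 3 and -0.16 in control replicate 2 and from -0.08 to 0.11 in the other libraries. Without BPA replicate 1 the median was -0.33. Without BPA replicate 3 it was -0.02, 29 of 47 members lay below control and the call ended (adjusted p 0.123, in a range over alternatives from 4.88e-13 to 0.820).

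**Figure D3:**
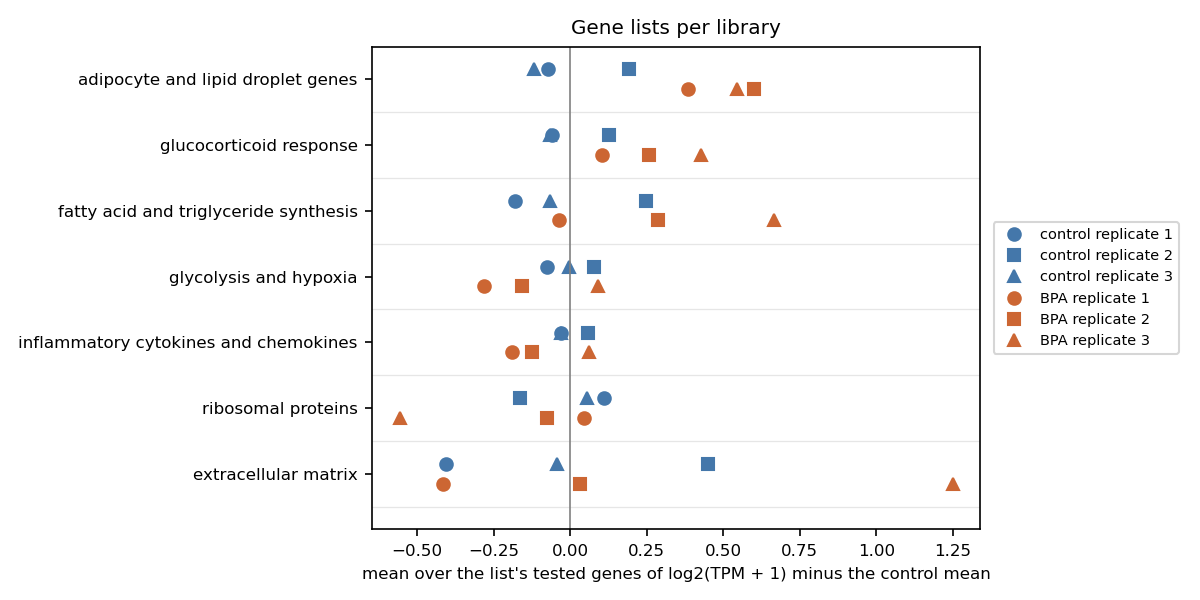
Mean over each list's tested genes of log2(TPM + 1) minus the control mean (horizontal axis, log2 units) in each library, for the 6 lists that passed camera with a preset correlation and for extracellular matrix genes (control in blue, BPA in orange). The adipocyte list runs from 0.38 to 0.60 with BPA and from -0.12 to 0.19 in control, while BPA replicate 3 lies at 1.25 for extracellular matrix genes and at -0.56 for ribosomal proteins.

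Extracellular matrix genes had their highest list mean in BPA replicate 3, at 1.25, then control replicate 2, at 0.45, with the other libraries from -0.42 to 0.03. With all libraries 38 of 42 members lay above control (median 0.29, adjusted p = 0.166). Leaving out BPA replicate 3 turned this, with 35 of 42 below control and a median of -0.18 (adjusted p = 0.0002, in a range over alternatives from 4.19e-05 to 0.958). Its adjusted p was then 0.713 with an estimated correlation. The list passed as higher without control replicate 2 (median 0.48), BPA replicate 1 (0.65) or BPA replicate 2 (0.43), but with an estimated correlation its adjusted p was from 0.784 to 0.892. Periostin (POSTN), a matrix protein of activated fibroblasts, averaged 240 ± 56.4 against 377 ± 38.6 TPM, with no overlap, while MFAP5 overlapped at 22.2 ± 4.59 and 26.8 ± 2.18 TPM. Matrix remodelling genes had 13 of 19 members above control (median 0.17, adjusted p = 0.712), and a median of -0.0054 without BPA replicate 3 (adjusted p = 0.0429, in a range over alternatives from 0.0429 to 0.966; adjusted p = 0.663 with an estimated correlation). SERPINE2 was the 1 member of this list that passed when adjusted over the list alone.

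Markers of other mesenchymal fates and cell types did not pass in camera with all 6 libraries, but smooth muscle and pericyte markers passed as lower without BPA replicate 3. Mesenchymal stem and preadipocyte markers had 13 of 21 members above control (median 0.10, adjusted p = 0.583), but a median of 0.0031 without BPA replicate 3 and of -0.0002 without control replicate 1. PDGFRA, a receptor of adipocyte progenitors, averaged 106 ± 19.3 against 74.7 ± 8.10 TPM, and tissue factor (F3) 317 ± 28.3 against 417 ± 22.0 TPM. Smooth muscle and myofibroblast markers had 9 of 15 above control (median 0.04, adjusted p = 0.271), but without BPA replicate 3 13 of 15 lay below (median -0.18, adjusted p = 1.74e-05, in a range over alternatives from 1.04e-05 to 0.990). Without control replicate 1 the list also passed as lower (median -0.07, adjusted p = 0.0294). With an estimated correlation the adjusted p without these libraries was 0.534 and 0.892. CNN1 averaged 199 ± 24.5 against 243 ± 14.0 TPM and TPM2 1346 ± 89.1 against 1630 ± 122 TPM, without overlap. Pericyte markers had 5 of 7 above (median 0.32, adjusted p = 0.972), but without BPA replicate 3 7 of 7 lay below (median -0.20, adjusted p = 0.0372, in a range over alternatives from 0.0192 to 0.989; adjusted p = 0.636 with an estimated correlation). Osteogenic markers had 4 of 6 above (adjusted p = 0.271), macrophage and myeloid markers 1 of 5 (adjusted p = 0.182), and thermogenic adipocyte genes 3 of 5 (adjusted p = 0.321), with CIDEA at 2.89 ± 0.99 against 1.35 ± 0.32 TPM. Leaving out a library put the osteogenic median, 0.12 with all, between 0.03 and 0.18, and the thermogenic median, 0.30 with all, between 0.12 and 0.50, both lowest without BPA replicate 3 and highest without BPA replicate 1. Too few members were tested for a camera test of chondrogenic (4), endothelial (3) and mesothelial and epithelial markers (2). KRT7, of the last list, averaged 6.70 ± 0.96 against 9.12 ± 0.62 TPM and passed when adjusted over the list alone. That adjustment covered only 2 genes, and over all genes its adjusted p by limma was 0.901. Lymphocyte, Schwann and nerve, and erythroid markers and mitochondrially encoded genes had 0 tested members.

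Hormone and xenobiotic genes also did not pass as lists with all 6 libraries. The oestrogen and androgen list had 10 of 15 members above control (median 0.15, adjusted p = 0.674), with the progesterone receptor PGR at 2.86 ± 0.12 against 3.66 ± 0.02 TPM. Without BPA replicate 3 the direction of this list turned, with 5 of 15 members above control and a median of -0.08, and without BPA replicate 1 the median was 0.36. The oestrogen receptors ESR1 and ESR2 and the related receptor ESRRG were under the filter and not tested. ESR1 averaged 0.0920 ± 0.0110 TPM with BPA and 0.0983 ± 0.0177 TPM in control, with overlapping libraries. The xenobiotic list had 9 of 13 above (median 0.25, adjusted p = 0.0776), and 8 of 13 without BPA replicate 3 (median 0.02). Without control replicate 2 it passed as higher (median 0.31, adjusted p = 0.0421, in a range over alternatives from 0.0024 to 0.815; adjusted p = 0.796 with an estimated correlation). SULT1A1, a sulfotransferase of phenols, averaged 81.8 ± 5.93 against 62.4 ± 4.39 TPM and NQO1 863 ± 22.5 against 728 ± 57.8 TPM, without overlap. The aryl hydrocarbon receptor AHR (3.58 ± 0.21 and 3.62 ± 0.29 TPM), its target CYP1B1 (223 ± 96.9 and 156 ± 29.5 TPM) and NOCT, a clock-controlled gene (3.46 ± 0.84 and 2.59 ± 0.40 TPM), overlapped between groups.

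Among metabolic and stress lists, insulin and glucose handling had 18 of 21 members above control, immediate early and heat shock genes 16 of 20, and nuclear-encoded oxidative phosphorylation 12 of 40. Each had an adjusted p of 0.0591 by camera, and their list means in BPA replicate 3 were 0.73, 0.79 and -0.31. That library set these directions: without it 7 of 21, 10 of 20 and 32 of 40 members lay above control, with medians of -0.06, -0.0033 and 0.07 against 0.18, 0.23 and -0.08 with all libraries. Without BPA replicate 1 the medians moved the other way, to 0.33, 0.42 and -0.19, and that of the adipogenic transcription factors to 0.73. These 3 lists and the adipogenic transcription factors passed, in the direction seen with all 6 libraries, when control replicate 2, BPA replicate 1 or BPA replicate 2 was left out. With an estimated correlation their adjusted p was then from 0.784 to 0.889. PIK3R1, a regulatory subunit of the insulin-activated lipid kinase, averaged 43.2 ± 0.65 against 34.4 ± 1.84 TPM. Cholesterol synthesis and uptake had 18 of 25 above (adjusted p = 0.269) and 13 of 25 without BPA replicate 3, with INSIG1 at 426 ± 53.7 against 311 ± 40.9 TPM. Fatty acid oxidation had 14 of 23 (adjusted p = 0.420) and the NRF2 oxidative stress response 16 of 23 (adjusted p = 0.412). Both passed as higher without BPA replicate 3 (medians 0.08 and 0.10, against 0.0034 and 0.02 without BPA replicate 1), with an adjusted p of 0.534 and 0.498 with an estimated correlation. Senescence and p53 targets had 13 of 18 above control (median 0.04, adjusted p = 0.464) and the circadian clock 13 of 17 (median 0.13, adjusted p = 0.321). These were 7 of 18 (median -0.02) and 9 of 17 (median 0.01) without BPA replicate 3, and without BPA replicate 1 the medians were 0.11 and 0.26. The interferon response had 15 of 28 above (adjusted p = 0.812), with ISG15 at 4.66 ± 1.33 against 8.79 ± 1.67 TPM. The unfolded protein response had 13 of 26 above (adjusted p = 0.704), complement and acute phase 7 of 13 (adjusted p = 0.564), proliferation 17 of 33 (adjusted p = 0.700), and cannabinoid, sphingolipid and eicosanoid genes 12 of 23 (adjusted p = 0.518). Of these 4 lists 10 of 26, 4 of 13, 22 of 33 and 10 of 23 members lay above control without BPA replicate 3. The medians of the interferon, unfolded protein, complement, proliferation and cannabinoid lists lay within 0.04 of 0 with all libraries and turned when some libraries were left out, the cannabinoid median with each of the 6. Adipokines and secreted hormones had 4 of 12 above (adjusted p = 0.327). In that list 2 members passed when adjusted over the list alone, ADIPOQ, higher, and C1QTNF3, lower at 267 ± 38.1 against 388 ± 21.9 TPM. Wnt and TGF-beta signalling had 11 of 23 above (adjusted p = 0.277). The Wnt list passed as lower without BPA replicate 3 (19 of 23 below, median -0.17) or control replicate 1 (median -0.06), with an adjusted p of 0.534 and 0.892 with an estimated correlation. Its median, -0.0032 with all libraries, was above 0 without control replicate 2 (0.07), control replicate 3 (0.01), BPA replicate 1 (0.18) or BPA replicate 2 (0.04). DKK1 passed when adjusted over the list alone, and the BMP antagonist GREM1 averaged 1241 ± 36.3 against 1533 ± 49.5 TPM. Camera pointed down while the median and the mean lay above 0 for the unfolded protein response, interferon, complement, smooth muscle, pericyte, proliferation and cannabinoid lists, and while the mean alone did for the Wnt and adipokine lists.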

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

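The first principal component as a covariate and the omission of 2 libraries (BPA replicate 3 and control replicate 2) were chosen after the data were seen. The 20 genes of smallest p kept their direction in all 395 combinations of gene and alternative. Since their groups did not overlap, leaving out a library could not turn them, so this is no independent evidence of an effect. The 6 lists that passed turned in 1 of 96 combinations, and lists that did not pass in 99 of 413. That contrast is no independent evidence either. Lists that passed were picked for their shift, and several of the others had medians near 0. The replicate block, the estimated correlation and fry also leave a list's median as it was. No scaling moved the median of all genes by over 0.1 (log2). Depth is unknown, so its limits could not be set.

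Genes past the threshold numbered 0 higher and 0 lower (439 unadjusted, limma, and 684 unadjusted without BPA replicate 3). Without a filter there were 3 higher and 3 lower, each listed at 0 TPM in every library of 1 group (MC1R and CCL4, chosen after their values were seen, and locus numbers). Array weights gave 3037 higher and 1592 lower. Their estimate did not converge and gave BPA replicate 2 a weight of 6489 and the others from 0.031 to 1.24. With the covariate 4 were lower (CA9, CXCL8, POSTN and DKK1). Leave-one-out gave 0 to 1 lower, the 1 being MIR29C-1 (chosen after its values were seen) without BPA replicate 3, and 2 were lower without both libraries. An unadjusted p under 0.05 gave 46 higher and 40 lower at 1.5-fold or more, and 9 and 7 at 2-fold or more.

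Against 3 lists higher and 3 lower, 6 were higher without a filter and 8 after quantile normalization. Leave-one-out gave 3 to 8 higher (8 without control replicate 2, 7 without BPA replicate 1 or 2, 5 without BPA replicate 3) and 2 to 7 lower (2 without BPA replicate 1, 5 without control replicate 1, 7 without BPA replicate 3). There were 5 lower without both libraries and 7 lower with the covariate. An estimated correlation and fry each gave 0 higher and 0 lower (4 and 3 lists unadjusted). The cause was not tested for these shifts.

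Leaving out a library turned the median of 18 of 32 lists, and 13 turned without BPA replicate 3. Those of lists that passed, with all libraries or without the 1 left out, ranged from -0.19 to 0.0028 for inflammatory genes (positive without BPA replicate 1), from -0.18 to 0.65 for extracellular matrix, from -0.0054 to 0.32 for matrix remodelling, from -0.18 to 0.20 for smooth muscle and from -0.20 to 0.72 for pericyte markers. The last 4 were negative without BPA replicate 3, and smooth muscle also without control replicate 1. With the covariate extracellular matrix was at -0.092, smooth muscle at -0.17 and pericyte markers at -0.10, and without both libraries smooth muscle was at -0.10. BPA replicate 3 had the highest mean on these last 4 lists; the cause was not tested further here. With an estimated correlation 0 lists passed under leave-one-out (smallest adjusted p = 0.243).

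With the replicate number as a block, 0 genes passed (264 unadjusted) and 6 lists were higher and 4 lower. Deviations from the group means correlated at 0.72, -0.44 and -0.23 between samples numbered 1, 2 and 3, and not every sample correlated best with its own number. This gave no evidence that the numbers pair the samples. With 3 samples per group and a first component of 79.8% of the variance, it cannot exclude pairing.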

Other observations

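Chosen only after the results were seen were the fits with the first principal component as a covariate, the test of treatment for the library that stood apart, the tests of the axis as the sole cause and of BPA replicate 3 alone for adipocyte genes, and the counts of genes in other splits. The first component was computed from the same values that were then tested. Fits with it take it as known, so their SEs, intervals and p-values leave out its own uncertainty.

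With the first component as a covariate, 4 genes passed, all lower with BPA, by limma with Benjamini-Hochberg adjustment: CA9 (log2 change -0.98, SE 0.06, adjusted p = 0.0283), DKK1 (-0.69, SE 0.04, adjusted p = 0.0283), POSTN (-0.52, SE 0.04, adjusted p = 0.0477) and CXCL8 (-0.79, SE 0.06, adjusted p = 0.0489). Each had all 3 BPA libraries below all 3 control libraries. Over all alternatives the adjusted p ranged from 0.0009 to 1.000 for CA9 and DKK1, from 0.0012 for CXCL8 and from 0.0017 for POSTN, each lowest with the array weights that did not converge. In that fit 7 lists were lower by camera with a preset correlation. Among them was Wnt and TGF-beta signalling (median -0.11, adjusted p = 7.6e-05, in a range over alternatives from 6.5e-06 to 0.972), with an adjusted p of 0.421 with an estimated correlation. With an estimated correlation 0 lists passed. Genes at an unadjusted p under 0.05 numbered 1945, against 439 without the covariate.

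BPA replicate 3 stood apart from the other libraries. If the treatment were the source, all BPA libraries were to lie on the same side of all control libraries on the first component. They did not: BPA replicates 1, 2 and 3 scored -29.9, -0.10 and 61.1. Control replicates 1, 2 and 3 scored -28.1, 11.3 and -14.4. The criterion against the treatment was not met either. BPA replicate 1 lay below every control library by 1.76 only, where the SD of the control scores was 20.01. The criteria thus left the treatment undecided. All BPA libraries received the same 1 µM BPA, however. Treatment alone therefore does not account for the gap between BPA replicate 3 and BPA replicates 1 and 2. Transcript length and base composition may both contribute: on hand-written lists, BPA replicate 3 minus the mean of the other BPA libraries was 0.555 higher for long than for short AT-rich genes (bootstrap 95% interval 0.471 to 0.826), 2.26 higher for long than for short GC-rich genes (2.09 to 2.43) and 2.04 higher for GC-rich than for AT-rich long genes (1.73 to 2.17), but only 0.336 higher for GC-rich than for AT-rich short genes (0.196 to 0.456), with 4 of 28 short GC-rich genes higher (median -0.29). Long AT-rich genes were themselves not raised in BPA replicate 3, with 15 of 33 higher (median -0.07). Their difference from short AT-rich genes came from the latter lying lower, with 0 of 17 higher (median -0.63). Of the long GC-rich genes 21 of 21 were higher. Since BPA replicate 3 is a single library, the bootstrap intervals hold no spread between libraries. Lengths and base contents were taken from general knowledge of the genes, not measured, and other technical sources such as RNA quality stay open. Control replicate 2 moved the same way on the long GC-rich list, with a median of 0.92 above the other controls, against 1.97 for BPA replicate 3 above the other BPA libraries.

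Adipocyte and lipid droplet genes were higher with BPA by camera with a preset correlation, a call lost with an estimated correlation (adjusted p = 0.323, and 0.526 with the covariate). The main axis between libraries as the sole cause was argued against, since the difference in the list's mean, 0.51 without the covariate, was 0.462 with it (SE 0.12, 95% interval of the linear model 0.091 to 0.832), while a part played by it stays open, since the list's median was 0.275 with the covariate against 0.55. For BPA replicate 3 alone as the cause, leaving it out gave a median of 0.331, but the criterion written first, camera with an estimated correlation, left it open with a p of 0.0622, and only a criterion added after that outcome was seen, a mean difference of 0.492 (interval 0.017 to 0.967), argued against it. Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, 1 gave as large a mean change, the real one at 0.510, and the highest other gave 0.383. An effect of BPA and cultures that differentiated to different degrees for other reasons both stay open.

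Glycolysis and hypoxia genes were lower with BPA by camera with a preset correlation, a call lost with an estimated correlation (adjusted p = 0.323, and 0.204 with the covariate). The main axis as the cause was argued against: with the covariate the median was -0.180, further from 0 than the -0.09 without it, 24 of 27 members lay below control, and the list's mean differed by -0.20 (interval -0.226 to -0.174). Without the covariate the interval of the mean's difference, -0.445 to 0.214, held 0. The narrow interval thus holds only given the covariate and is no firm measure of a decrease. Of the 10 splits, too few for a share under 0.05, 5 gave as large a mean change, with the real one at 0.116 and the highest other at 0.227. An effect of BPA stays open, as do culture density and medium oxygen, for which the labels give no value.

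The 10 splits are also too few for a share under 0.05 for the counts. For genes past the adjusted threshold 10 of 10 splits gave as many, with 0 in the real split and 2 in the highest other. For genes at an unadjusted p under 0.05 there were 3 such splits, with 439 in the real one and 3371 in the highest other, which set control replicates 1 and 3 and BPA replicate 1 against the rest and so followed the first component, a structure of the samples. With the first component as a covariate 1 split gave as many, the real one with 1945, and the highest other had 885. For lists past the adjusted threshold there were 8, with 6 lists in the real split and 13 in the highest other.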
